A study of Mus musculus with 68 samples.

How the data were processed

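The series held 68 lung samples of male C57BL/6J and CAST/EiJ mice in clean air or under BD. They were 24 RNA-seq, 20 small RNA-seq and 24 chromatin accessibility (ATAC-seq) samples. No file of the ATAC-seq samples was at hand, and they were not analysed here. The RNA-seq table held read counts per gene symbol, which the authors made by aligning reads with GSNAP to mouse build mm9, per the submitters' processing notes. The small RNA table held estimated counts per mature miRNA and locus, fractional where reads were shared, which the authors made by aligning reads with Bowtie to mm9, per the submitters' processing notes. Versions of both aligners, the counting tools and their annotation were not given in the sources used here. Every column of both tables was matched to a sample by title.

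The RNA-seq table held 23893 entries, of which 21 had no value in any library labelled CAST/EiJ. All 21 were Y-linked in the RefSeq table at hand (23765 symbols, assembly GRCm38.p6), which was used for names and chromosomes only because its build differs from mm9. The 23872 complete entries were used, and 985 of them, in 284 sets, were identical in every library to another entry. The small RNA table held 480 miRNAs, 160 of them without a value in at least 1 library and with a smallest listed value of 10.5. Of the listed values 64.1% were whole within 1e-06. The 320 complete miRNAs, which held at least 98.4% of each library, were rounded to whole counts and tested. Over all 276 pairs of RNA-seq libraries and 190 of small RNA libraries, the smallest chi-square per degree of freedom was 5.20 and 20.7. So no 2 libraries were copies.

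Libraries were grouped by strain and exposure within each assay, and 1 model with 1 mean per group was fitted per assay. edgeR 4.0.16 in R 4.3.3 was used, with filterByExpr, TMM scaling, robust dispersions and quasi-likelihood F tests, and p-values were adjusted by Benjamini-Hochberg within each comparison. Adjusted p under 0.05 was called. The comparisons were BD against clean air in each strain, CAST/EiJ against C57BL/6J in clean air and under BD, and the interaction, which is the BD ratio in CAST/EiJ divided by that in C57BL/6J. Levels were printed as CPM (counts per 1e+06) of the TMM-scaled library with standard deviations (SD) over libraries. The fold changes came from the same fit. For each contrast the median log2 fold over genes moved by less than 0.02 when median-of-ratios factors replaced TMM. The p-values measured the spread within groups, pooled over all groups, in which animal, dissection and library preparation are not separable.

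A fixed rule chose the genes that were named, written before the data were examined. Among called genes with a mean of at least 1 CPM in a compared group, the 8 highest and 8 lowest folds and the 4 smallest remaining p-values were taken, for miRNAs 5, 5 and 3 from a mean of 5 CPM. Symbols of predicted or unnamed genes were passed over. In the clean-air strain comparison genes also needed ranges of CPM that did not overlap between strains, and the comparison under BD took over its names. Cyp2e1, Ephx1, Gstt1, Gstm1 and Cdkn1a were always reported, and up to 2 members per direction of each list that passed. For genes without counts in 1 group a lower bound of the fold was given from a floor of 3 counts per library, and named genes with a clean-air mean under this floor were also set against it. The same rule was applied again to the fit without library number 8 after the data had been seen.

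Gene lists for exposure, damage response, repair, immune and lung cell types were written from general knowledge, 41 of which had members in the RNA-seq table and 14 in the small RNA table. The list of mitochondrially encoded genes and the Sfmbt2 miRNA cluster had no members in the tables. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, and adjusted over the lists of a comparison. Members counted as risen or fallen passed over all genes, and counts adjusted over the list alone are given beside them. Overlaps of called genes were tested by Fisher's exact test against the tested genes. A strain index was built from the genes or miRNAs with the clearest clean-air strain difference, and libraries were also arranged by principal components (50.2%, 14.1% and 9.23% of the variance in RNA-seq, and 38.0%, 19.9% and 12.3% in small RNA).

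The steps were tested on simulated data drawn from the real means and library sizes. For BD in C57BL/6J (17223 genes) 74.6% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 100% of those changed 4-fold were recovered, with 9 false calls among 184. For BD in CAST/EiJ (17228 genes) the shares were 71.6%, 98.5% and 100%, with 7 false among 187, and for the clean-air strain comparison (17224 genes) 59.7%, 88.1% and 98.5%, with 5 false among 169. For miRNAs (320) 70.0% and 96.7% of 1.5-fold and 2-fold changes were recovered for BD in C57BL/6J, 70.0% and 93.3% for BD in CAST/EiJ and 73.3% and 90.0% between strains, with 0, 1 and 2 false among 50, 50 and 51 calls. Each time a list of raised genes was called and 0 of 40 unchanged lists were, with no gene correlation from real data. A gene at 1 CPM had about 10 counts in the smallest RNA-seq library.

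The alternatives were median-of-ratios factors, no filter on low counts, DESeq2 1.42.0, limma-voom for the interaction, a fit of the compared groups alone and each library left out in turn. Libraries with title numbers over 100 were left out, or that number series was made a covariate. Lists were also tested with an estimated inter-gene correlation and with fry. After the data were seen, fits without library number 8 (CAST/EiJ BD replicate 5 in RNA-seq and replicate 3 in small RNA), alone and with these settings, were added. So were a covariate for the split of the small RNA libraries by number (1 to 10 against the others), squamous and liver scores as covariates, and unlisted miRNA values taken as 0 or 5. Library number 8 was kept under its label in all tests unless stated, and the number-matched correlations were run without and with it. To weigh chance, 100 splits of the libraries into the same group sizes were tested, the real one included, or all 35 where fewer existed.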

Results

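Lungs of male C57BL/6J and CAST/EiJ mice that breathed clean air or 1,3-butadiene (BD, given 6 h per day on weekdays for 2 weeks) were measured by RNA-seq in 24 libraries and by small RNA-seq in 20 libraries. The RNA-seq groups held 5 (C57BL/6J, clean air), 6 (C57BL/6J, BD), 7 (CAST/EiJ, clean air) and 6 libraries (CAST/EiJ, BD), and the small RNA groups held 5, 4, 7 and 4. RNA-seq libraries held 10601756–50001571 counts and small RNA libraries 2066588–8474182. Of 23872 genes with a value in every library, 17371 passed the filter on low counts, and 320 miRNAs were listed in every small RNA library. Fold changes and adjusted p-values came from edgeR. The p-values measured replicate spread over all groups, technical spread included.

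To determine how the libraries were arranged before any exposure was compared, each was placed on a strain index, with 0 at the clean-air C57BL/6J level and 1 at the clean-air CAST/EiJ level. The library labelled CAST/EiJ BD replicate 5 (title number 8) stood at 0.116 in RNA-seq, against 0.868–0.967 in the other 5 CAST/EiJ BD libraries and from -0.0789 to 0.185 in the C57BL/6J libraries. The small RNA library of the same number stood at 0.171, against 0.816–0.851 in its group. Iigp1, an interferon-inducible GTPase, was measured at 66.4 CPM in library number 8, at 79.3 ± 19.1 CPM (SD, n = 5) in clean-air C57BL/6J and at 0.0468 ± 0.0559 CPM (SD, n = 5) in the other CAST/EiJ BD libraries. A 2nd arrangement followed the numbers of the titles. Numbers over 100 were held by 5 of 7 clean-air CAST/EiJ libraries, by 1 of 5 clean-air C57BL/6J libraries and by no BD library. Cytosolic ribosomal protein genes were higher in the numbers over 100, by a median log2 difference of 0.46 against numbers 1 and 2 in CAST/EiJ and of 0.44 against numbers 3 to 6 in C57BL/6J.

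**Figure D1:**
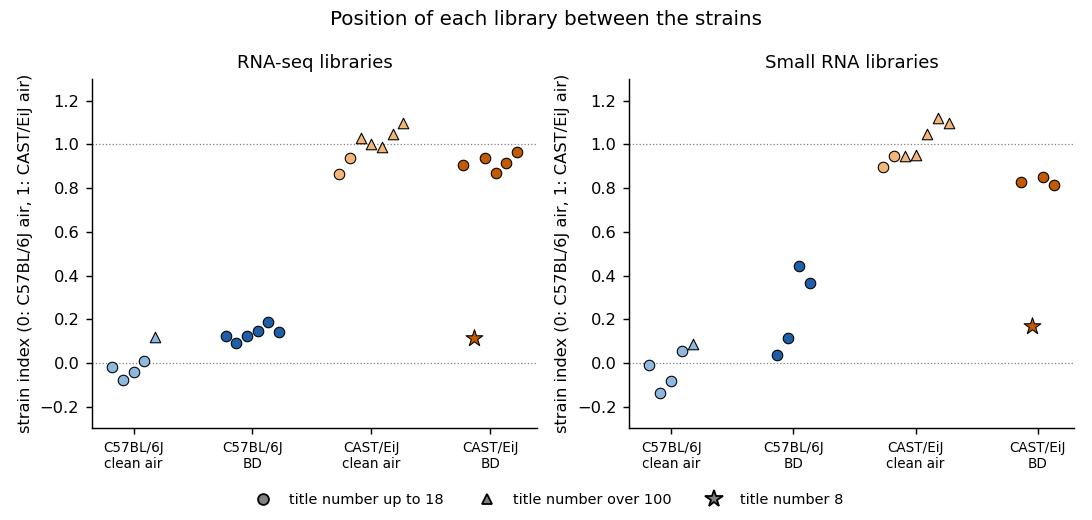
Each point is 1 library, placed by its strain index within its labelled group. Library number 8, drawn as a star, lay at 0.116 (RNA-seq) and 0.171 (small RNA) in the CAST/EiJ BD group.

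To determine how BD changed the lung of C57BL/6J mice, 6 BD libraries were compared with 5 clean-air libraries. Genes of the glutathione and thioredoxin defence rose. Srxn1, which encodes sulfiredoxin, rose 2.91-fold, from 23.7 ± 2.01 (SD, n = 5) to 68.9 ± 5.50 CPM (SD, n = 6; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.07e-08). Gclc, the catalytic subunit of glutamate-cysteine ligase, rose 2.83-fold from 208 ± 21.7 (SD, n = 5) to 589 ± 81.1 CPM (SD, n = 6), Nqo1 rose 2.71-fold and Gsta3 2.32-fold. The glucocorticoid-responsive genes Fkbp5 and Zbtb16 rose 4.77-fold and 3.61-fold, and Fam107a showed the highest fold of the named genes that passed with all libraries, 5.62, from 9.91 ± 2.76 (SD, n = 5) to 56.5 ± 14.9 CPM (SD, n = 6). Cdkn1a, the p53-induced cell cycle inhibitor p21, rose 2.27-fold from 10.9 ± 3.45 (SD, n = 5) to 24.9 ± 8.41 CPM (SD, n = 6). The immediate early genes Egr1, Nr4a3 and Nr4a1 fell 4.40-fold, 3.91-fold and 3.60-fold, with Egr1 at 49.2 ± 28.7 CPM (SD, n = 5) in clean air and 11.1 ± 1.75 CPM (SD, n = 6) under BD.

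In total 1298 of 17371 genes passed an adjusted p of 0.05 in C57BL/6J, of which 489 rose and 809 fell, and 165 changed at least 2-fold. Among the 8 highest folds were also the stress cytokine Gdf15 (4.55-fold), the carboxylesterases Ces1g (4.01-fold) and Ces1a (3.67-fold), Doc2b (3.27-fold) and the macrophage scavenger receptor Marco (3.10-fold). Pou2f2, a transcription factor of B cells, fell 3.69-fold, Klhl14 3.41-fold, Fbn2 3.28-fold and the interleukin 5 receptor Il5ra 3.20-fold. The circadian repressor Nr1d1 fell 3.61-fold (adjusted p = 0.0251). Of the enzymes that handle BD and its epoxides, Ephx1 (1.39-fold), Gstt1 (1.37-fold) and Gstm1 (1.35-fold) rose, whereas Cyp2e1 did not pass (adjusted p = 0.602). The number of genes was 570 without clean-air replicate 3, 753 without clean-air replicate 4, and 768, 736 and 718 without BD replicates 3, 4 and 5. Nr1d1 did not pass without any 1 of these 5 libraries (adjusted p 0.0574–0.0799). Without clean-air numbers over 100, 1971 genes passed, 960 higher and 1011 lower, and 1168 of them were among the 1298. With the number series as a covariate 1100 rose and 1342 fell. Cyp1a1, the aryl hydrocarbon receptor target, was 7.85-fold higher under BD, at 78.0 ± 58.9 CPM (SD, n = 6) against 9.96 ± 0.909 CPM (SD, n = 5). It did not pass with all libraries (adjusted p = 0.0971) and passed without number 8 (0.000163; range over 33 alternatives 0.000163–0.194).

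By gene list in C57BL/6J, 25 of 52 tested glutathione and NRF2 targets rose and none fell (34 rose adjusted over the list alone; camera adjusted p = 3.73e-22, and adjusted p = 0.0137 with an estimated correlation). Butadiene bioactivation and phase I enzymes rose in 14 of 42 cases, among them Ces1g and Aox1 (1.95-fold), and 1 fell (16 and 1 adjusted over the list alone; adjusted p = 1.00e-10, and adjusted p = 0.0137 with an estimated correlation). The member that fell was Cyp4f18 (1.53-fold), whose call ended on leaving out any of 17 libraries (adjusted p 0.0525–0.193). Of 44 p53 targets 15 rose, among them the apoptosis effector Bax (1.46-fold) and Gtse1 (2.58-fold), and 2 fell (the same counts adjusted over the list alone; adjusted p = 1.23e-05, and adjusted p = 0.0365 with an estimated correlation). The p53 targets that fell, Btg2 (1.52-fold) and Plk2 (1.52-fold), are also induced by growth signals, and Btg2 stands on the immediate early list. The lists for cell cycle and proliferation (19 of 50 rose, Prc1 1.65-fold and Rrm1 1.28-fold, 35 rose and 1 fell adjusted over the list alone) and for the glucocorticoid response (12 of 20 rose, 15 rose and 1 fell adjusted over the list alone) moved up with adjusted p of 2.69e-16 and 2.67e-13. Their adjusted p was 0.106 and 0.0736 with an estimated correlation. Other lists moved up through few members, namely alveolar macrophage markers (2 of 20, Marco among them, 2 adjusted over the list alone; adjusted p = 0.0156, and adjusted p = 0.464 with an estimated correlation), nucleotide excision repair (3 of 30, 3 adjusted over the list alone; 0.00436, and 0.205 with an estimated correlation) and oxidative phosphorylation (0 of 42, 0 adjusted over the list alone; 0.00022, and 0.741 with an estimated correlation).

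Lymphoid markers fell in C57BL/6J under BD. Of 23 B and plasma cell markers 12 fell and none rose (19 fell adjusted over the list alone), among them Fcrla (2.73-fold) and the B cell factor Ebf1 (1.61-fold, adjusted p = 0.0112, and 0.0513 without clean-air replicate 3). Of 34 T and NK cell markers 5 fell, with Cd2 (1.70-fold) and Ccr7 (2.35-fold) as examples (13 adjusted over the list alone), of 34 MHC genes 4 fell, H2-Ab1 among them (1.59-fold, 7 adjusted over the list alone), and of 27 immediate early genes 12 fell (16 adjusted over the list alone). These lists moved down with adjusted p of 1.35e-11, 7.00e-09, 3.00e-07 and 1.71e-10, and with an estimated correlation the adjusted p was 0.238, 0.422, 0.464 and 0.114. Dendritic cell markers (4 of 22 fell, 1 rose and 9 fell adjusted over the list alone; adjusted p = 8.43e-05), interferon-stimulated genes (1 of 45, Parp14, 1.35-fold, 1 adjusted over the list alone; 3.04e-05) also moved down. Further lists that moved down were cholesterol synthesis (3 of 29, Stard4 1.41-fold, 1 rose and 3 fell adjusted over the list alone; 0.033), chromatin modifiers (5 of 48, Tet3 1.52-fold, 2 rose and 6 fell adjusted over the list alone; 0.043) and eosinophil, basophil and mast cell markers (2 of 14, Il5ra among them, 1 rose and 3 fell adjusted over the list alone; 0.043, and 0.0507 without number 8). With an estimated correlation the adjusted p of these 5 was 0.332, 0.589, 0.589, 0.767 and 0.422. The other 24 lists did not pass, from hypoxia response (adjusted p = 0.0512) to the markers of AT1, club and basal cells (0.977 each). They included double-strand break repair (0.117), base excision repair (0.571), inflammatory cytokines (0.0795) and the circadian clock (0.472).

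**Figure D2:**
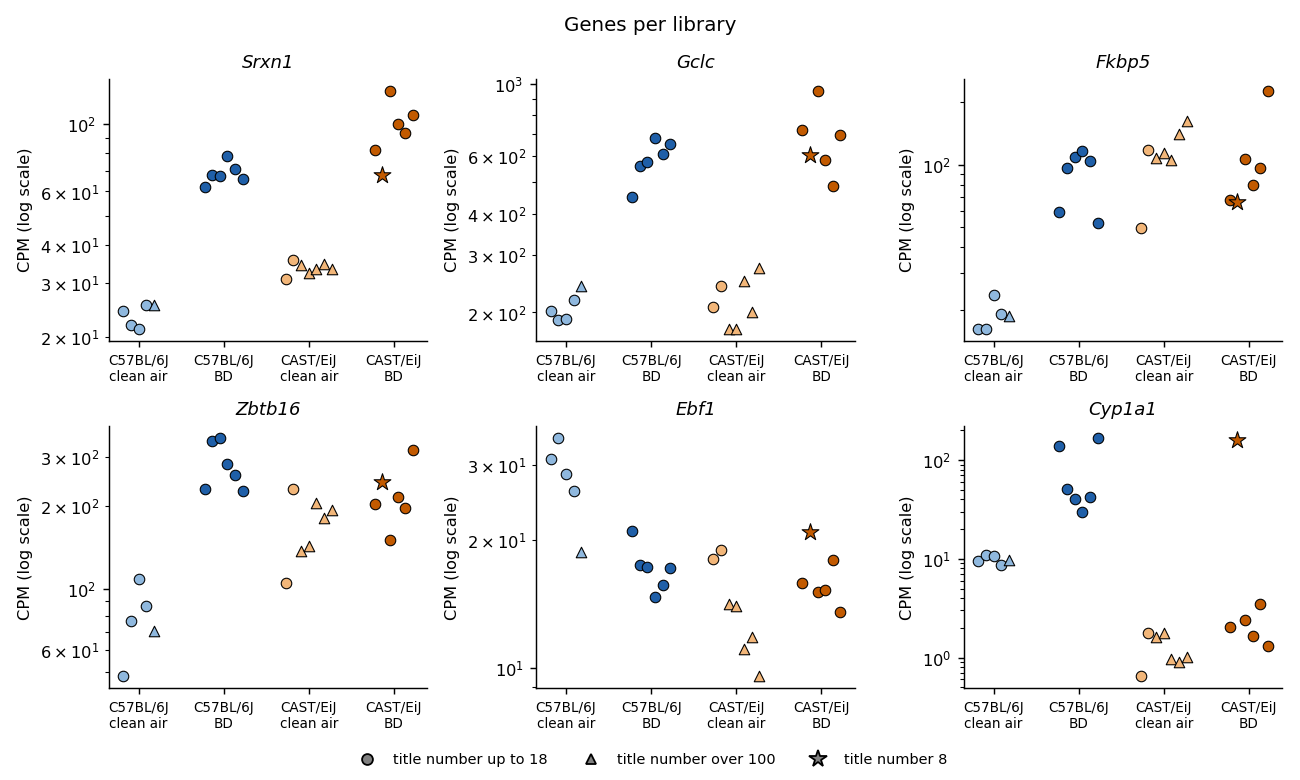
Each point is the level of 1 gene in 1 RNA-seq library, in CPM on a log scale. Srxn1 and Gclc were higher under BD in both strains, and Cyp1a1 in library number 8 (162 CPM) lay among the C57BL/6J BD libraries.

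To determine how BD changed the lung of CAST/EiJ mice, the 6 libraries labelled CAST/EiJ BD were compared with 7 clean-air libraries. Several thioredoxin and glutathione genes rose, among 20 of 52 members of their list, whereas Gpx1 fell and the list did not pass with an estimated correlation (adjusted p = 0.449). Srxn1 rose 2.87-fold from 33.6 ± 1.59 (SD, n = 7) to 96.5 ± 20.8 CPM (SD, n = 6; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.05e-09), Gclc 3.09-fold from 218 ± 36.8 (SD, n = 7) to 675 ± 159 CPM (SD, n = 6), and Txnrd1, thioredoxin reductase 1, 2.38-fold from 64.4 ± 8.35 (SD, n = 7) to 153 ± 29.3 CPM (SD, n = 6). Gstm1 rose 1.61-fold. The cystine transporter Slc7a11 rose 4.29-fold (adjusted p = 0.00027) and the anion exchanger Slc26a4 rose from 2.49 ± 0.868 (SD, n = 7) to 12.4 ± 7.46 CPM (SD, n = 6; adjusted p = 0.00288), and without clean-air numbers over 100 neither passed (adjusted p = 0.0584 and 0.207, the highest over 33 alternatives). Without number 8 the highest folds included Eid3 (3.40-fold) and the NRF2-responsive genes Osgin1 (2.81-fold) and Tsku (2.22-fold), and each of the 3 passed in all 33 alternatives, with adjusted p up to 0.0222, 0.00482 and 0.0066. Ephx1 (adjusted p = 0.803), Gstt1 (0.97), Cdkn1a (1.22-fold, 0.418) and Cyp2e1 (0.589) did not pass.

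In total 2390 genes passed in CAST/EiJ, of which 1285 rose and 1105 fell, and 205 changed at least 2-fold, against 94 without number 8. The 8 highest folds all came from library number 8: Iigp1 (69.0-fold), Fam183b (31.5-fold), Olfr1033 (24.3-fold), Cyp1a1 (22.7-fold), Gabra3 (18.5-fold), Tmem132d (14.2-fold), Trim30d (12.3-fold) and Krt79 (8.24-fold). Against the floor of 3 counts per library in clean air, the folds were 62.7 for Iigp1, 10.7 for Fam183b, 8.53 for Olfr1033, 13.5 for Gabra3 and 12.1 for Tmem132d. Cyp1a1 was at 162 CPM in number 8 and at 2.18 ± 0.851 CPM (SD, n = 5) in the other 5 BD libraries, and without number 8 none of the 8 passed (adjusted p 0.0921–0.911). There the log2 folds of Iigp1, Gabra3 and Krt79 changed sign (-1.88, -0.82 and -0.11), that of Krt79 with group means of 0.389 CPM in clean air and 0.394 CPM under BD. The lowest folds were those of Keg1 (7.73-fold), Krt17 (4.92-fold), the RNA component gene Rprl2 (4.63-fold), the secreted airway protein Bpifa1 (3.94-fold, 802 ± 514 CPM, SD, n = 7, to 204 ± 145 CPM, SD, n = 6), Scand1 (3.77-fold), Cyp4a12a (3.47-fold) and the small nucleolar RNA genes Snord49b (3.32-fold) and Snord89 (3.22-fold). Of these Rprl2, Scand1, Snord49b and Snord89 passed whichever single library was left out, but none of the 4 passed without numbers over 100 (adjusted p = 0.334, 0.809, 0.16 and 0.23), and over 33 alternatives their adjusted p reached 0.446, 0.809, 0.225 and 0.23. Without number 8 Krt17 (adjusted p = 0.0581), Cyp4a12a (0.0823) and Keg1 (0.0874) did not pass. Krt17 also ended without BD replicate 1 (0.0516), and Bpifa1 without BD replicates 2, 4 and 6 or clean-air replicates 4, 5 and 7 (up to 0.065). Cyp4a12a ended on leaving out any of 7 libraries (up to 0.175, without clean-air replicate 7, whose liver marker score was 6.95 against -0.26 to 3.32 in the other clean-air CAST/EiJ libraries) and Keg1 on any of 20 (up to 0.0874). Clean-air replicate 4 ended 11 of the calls of this comparison (adjusted p 0.0537–0.0799), and clean-air replicates 1, 2, 3 and 5 ended 4, 7, 5 and 7 (up to 0.066, 0.0665, 0.0684 and 0.0711).

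The number of genes in CAST/EiJ moved with single libraries and with the number series. It was 1255 without number 8, with 1079 of the genes shared. It was 1291, 1246, 1463, 808 and 1127 without clean-air replicates 1 to 5 in turn, and 3810 without clean-air replicate 6. Without numbers over 100, 382 genes passed, 43 of them higher and 339 lower, and 96 were among the 2390. With the number series as a covariate 200 passed, and 275 with the covariate and without number 8. With the 2 CAST/EiJ groups alone in the fit 159 passed. Of the named genes, 35 of 50 calls ended without numbers over 100, 35 of 50 with the series as a covariate and 25 of 43 with the 2 groups alone. Srxn1, Gclc, Txnrd1, Gstm1 and Osgin1 passed in all 33 alternatives.

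By gene list in CAST/EiJ, 20 of 52 glutathione and NRF2 targets rose and 1 fell, Gpx1 (1.42-fold), which encodes the most abundant glutathione peroxidase (22 and 1 adjusted over the list alone; camera adjusted p = 6.98e-07, and adjusted p = 0.449 with an estimated correlation). Of 44 p53 targets 7 rose, Zmat3 (1.56-fold) and Mdm2 (1.21-fold) among them (7 adjusted over the list alone; adjusted p = 0.0253, and adjusted p = 0.449 with an estimated correlation). Chromatin modifiers (15 of 48 rose, Crebbp 1.51-fold and Kdm5b 1.18-fold, 21 adjusted over the list alone; adjusted p = 3.39e-07, and 0.449 with an estimated correlation), cell cycle (4 of 50 rose, 0 adjusted over the list alone; 0.000686, and 0.767 with an estimated correlation) and double-strand break repair (9 of 60 rose, Bard1 1.55-fold and Chek2 1.36-fold, and Nbn fell 1.24-fold, 16 rose and 2 fell adjusted over the list alone; 0.0103, and 0.767 with an estimated correlation) moved up. Cell cycle and double-strand break repair did not pass without numbers over 100 (0.429 and 0.742; ranges over 6 alternatives 0.000911–0.767 and 0.0163–0.904). T and NK cell markers moved up with all libraries (3 of 34 rose, Prf1 1.71-fold, 3 adjusted over the list alone; adjusted p = 0.0394, and 0.859 with an estimated correlation) and did not pass without number 8 (0.853, with the test turned downward).

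Cytosolic ribosomal proteins and oxidative phosphorylation fell in CAST/EiJ. Of 48 ribosomal protein genes 25 fell, Rps20 (1.38-fold) and Rpl30 (1.29-fold) among them (42 adjusted over the list alone; adjusted p = 1.12e-14, and adjusted p = 0.449 with an estimated correlation), and of 42 oxidative phosphorylation genes 14 fell, among them Ndufs7 (1.44-fold), a complex I subunit (33 adjusted over the list alone; adjusted p = 4.66e-13, and 0.449 with an estimated correlation). Without numbers over 100 ribosomal proteins (0.252; range over 6 alternatives 1.24e-11–0.449), cholesterol synthesis (0.179) and fibroblast markers (0.742) did not pass. Cholesterol synthesis (9 of 29 fell, Sqle 1.38-fold and Sc4mol 1.51-fold, 11 adjusted over the list alone; adjusted p = 0.000686, and 0.449 with an estimated correlation), heat shock and unfolded protein response (6 of 32 fell, Pdia6 1.35-fold and Xbp1 1.28-fold, and the stress-induced Chac1 rose 2.31-fold, 1 rose and 11 fell adjusted over the list alone; 0.000948, and 0.767 with an estimated correlation) and smooth muscle markers (5 of 20 fell, Kcnj8 1.74-fold and Tagln 1.56-fold, and 1 rose, 1 rose and 9 fell adjusted over the list alone; 0.0142, and 0.449 with an estimated correlation) also moved down. So did fibroblast markers (5 of 21 fell, Dpt 1.37-fold and Pi16 1.64-fold, 1 rose and 8 fell adjusted over the list alone; 0.0204, and 0.449 with an estimated correlation) and neuroendocrine markers (1 of 15, 1 adjusted over the list alone; 0.0245, and 0.449 with an estimated correlation). Club cell markers fell in 6 of 20 cases, the secretoglobin Scgb3a1 (2.83-fold) among them (6 adjusted over the list alone; adjusted p = 0.0122, and 0.767 with an estimated correlation). Ciliated cell markers had a median log2 fold of -0.18, a mean of 0.03 and a test pointing down (3 of 24 fell, Spag6 1.59-fold and Tekt4, and Fam183b rose through number 8, the same adjusted over the list alone; 0.0209, and 0.859 with an estimated correlation). The other 26 lists did not pass, from MHC genes (adjusted p = 0.0996) to the glucocorticoid response (1), and they included phase I enzymes (0.836, 4 rose and 4 fell), immediate early genes (0.528) and B and plasma cell markers (0.258).

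**Figure D3:**
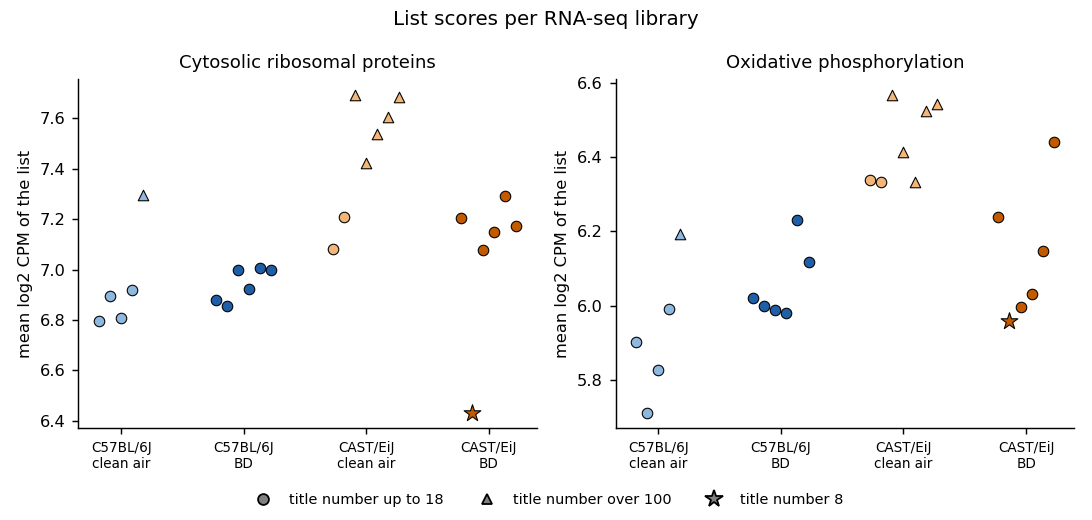
Each point is the mean log2 CPM of a gene list in 1 RNA-seq library. Within clean air the numbers over 100 lay higher for ribosomal proteins, by a median log2 difference of 0.46 in CAST/EiJ.

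To determine whether BD moved the same genes in both strains, the 1298 and 2390 genes were overlapped. Of the genes that rose in C57BL/6J 21.1% also rose in CAST/EiJ, against 7.4% by chance (odds ratio 3.54, 95% interval 2.80–4.45, Fisher exact p = 8.13e-23), whereas 32 genes fell in both, against 51.5 by chance (odds ratio 0.595, Fisher exact p = 0.00307). Without number 8 14.1% of the genes that rose were shared, against 3.86% by chance (odds ratio 4.66), and without numbers over 100 3.23% against 0.242% (odds ratio 46.8, 31 shared of 960). The excess of shared genes that rose thus held its direction but not its size, whereas the odds ratio of the genes that fell did not hold its direction. The latter was 1.09 without number 8 (Fisher exact p = 0.608) and 0.396 without numbers over 100 (Fisher exact p = 0.00433). Another 48 moved in opposite directions, against 17 without number 8 and 1 without numbers over 100. Srxn1, Gclc and Gstm1 were among the genes that rose in both. Across genes, which are not independent replicates, the fold changes of both strains correlated at r = 0.0943 (Spearman -0.0841). These were 0.164 and -0.0199 without number 8, and 0.262 and 0.0668 without numbers over 100, where the shared genes numbered 39.

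**Figure D4:**
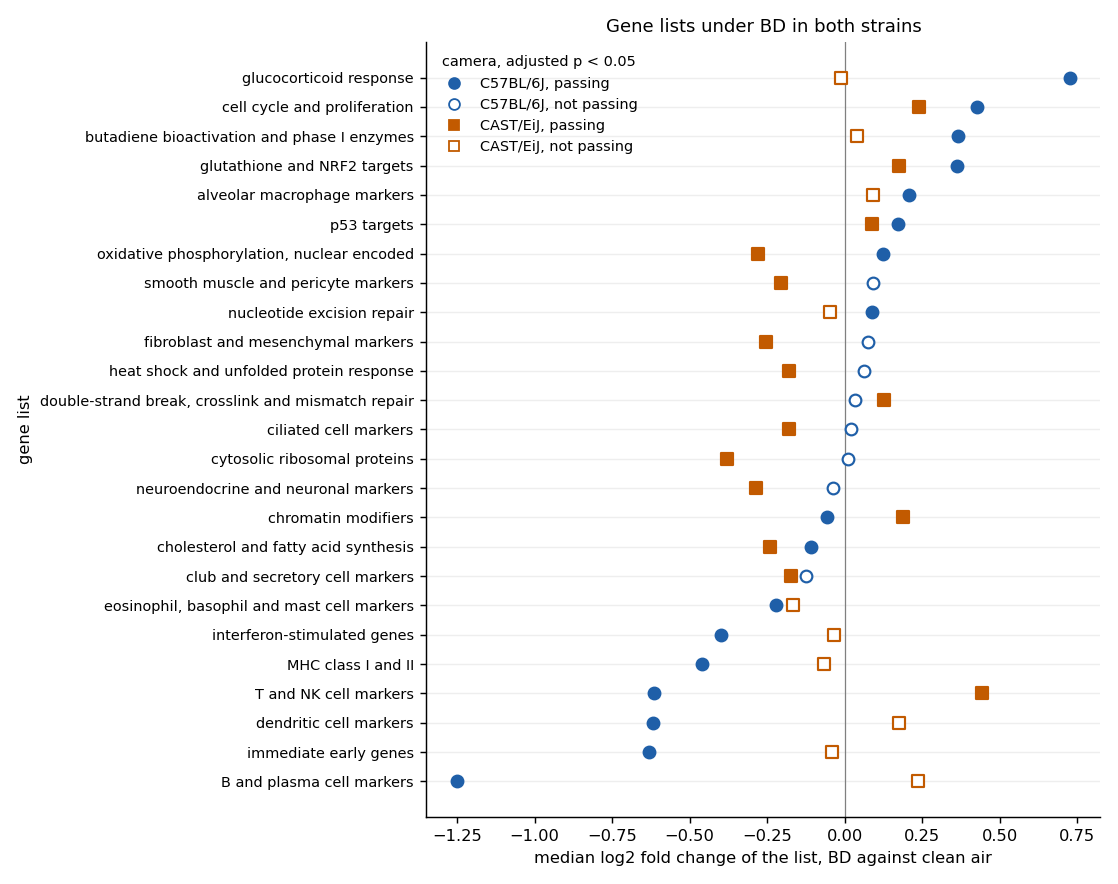
Each row is a gene list that passed in at least 1 strain, and its points are the median log2 fold changes under BD in C57BL/6J and CAST/EiJ. Glutathione and NRF2 targets, p53 targets and cell cycle genes passed upward in both strains with the preset correlation. Cell cycle genes passed in neither strain with an estimated correlation (adjusted p = 0.106 in C57BL/6J and 0.767 in CAST/EiJ), and the other lists did not pass in CAST/EiJ (0.449 each).

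To determine which genes differed between the strains before exposure, 7 clean-air CAST/EiJ libraries were compared with 5 clean-air C57BL/6J libraries. Immune genes were among those that differed. Iigp1 was 505-fold lower in CAST/EiJ, at 0.159 ± 0.0934 CPM (SD, n = 7) against 79.3 ± 19.1 CPM (SD, n = 5; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 8.88e-05), and the C-type lectin Clec12b was 312-fold lower. The complement gene Hc was lower, at 68.6 ± 12.8 (SD, n = 7) against 895 ± 126 CPM (SD, n = 5), and the T cell coreceptor Cd8a was 5.45-fold lower. H2-Ea-ps, a class II pseudogene locus of C57BL/6J, was 658-fold higher in CAST/EiJ, and the kininogen Kng2 was 173-fold higher. Fitted folds of genes whose lower mean lay under the floor of 3 counts per library are unstable. Set against that floor, these folds were 448 for Iigp1, 35.8 for Clec12b and 637 for H2-Ea-ps. Cdkn1a was 2.31-fold higher in CAST/EiJ (10.9 ± 3.45 CPM, SD, n = 5, to 25.4 ± 5.94 CPM, SD, n = 7), a clean-air level near that of C57BL/6J under BD.

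In clean air 10316 of 17371 genes passed between the strains, 5028 higher and 5288 lower in CAST/EiJ, and 2675 at least 2-fold. Without numbers over 100, 6820 passed, 6024 shared. Other genes with the highest folds were Ear11 (435-fold), Lcn8 (306-fold), Rprl2 (274-fold), Amer1 (210-fold) and Nkain3, which had no counts in clean-air C57BL/6J and was at least 10.6-fold higher in CAST/EiJ against a floor of 3 counts per library. Ddx3x also had no counts in clean-air C57BL/6J and was at 598 ± 36.6 CPM (SD, n = 7) in CAST/EiJ, at least 3385-fold higher. Ddx3x and Amer1 were at 524 and 56.9 CPM in number 8, as in others of its label, so their strain differences are uncertain. Most other calls and the lists were not tested for this. Fam183b (206-fold), Wfdc17 (166-fold), Skint3, Cd209f (122-fold), Tmem132d (115-fold) and Olfr1033 were lower in CAST/EiJ, and without numbers over 100 Cd209f (adjusted p = 0.0721) and Olfr1033 (0.0593) did not pass, the highest values over their 32 alternatives. The smallest p-values were those of Rpl21 (5.69-fold lower), the Mir692 copies 2a and 2b (9.28-fold higher) and Rpl35a (4.68-fold lower), whose levels in number 8 (12.6, 87.3 and 15.6 CPM) also lay with its label, so that their folds are uncertain. Against the floor of 3 counts per library the folds were 86.4 for Ear11, 27.2 for Lcn8, 67.5 for Rprl2, 66.3 for Fam183b, 19.7 for Wfdc17, 29.3 for Skint3, 14.2 for Cd209f, 94.4 for Tmem132d and 34.1 for Olfr1033. Retsat (7.85-fold higher) and Trim12a (22.5-fold lower) were further named differences. Cyp2e1 (adjusted p = 0.119), Ephx1 (0.121), Gstt1 (0.162) and Gstm1 (0.7) did not pass, although Cyp2e1 passed as higher in CAST/EiJ without numbers over 100 (0.0204), Ephx1 passed without clean-air CAST/EiJ replicate 6 (0.00881) and Gstt1 without clean-air C57BL/6J replicate 1 (0.036).

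By gene list, lymphocyte markers were lower in clean-air CAST/EiJ. Lower were 32 of 34 T and NK cell markers (Cd8a, and Lef1 2.85-fold; camera adjusted p = 8.24e-11) and 20 of 23 B and plasma cell markers (Fcer2a 6.55-fold and Cd22 7.38-fold; 1.60e-05), with the plasma cell marker Sdc1 1.27-fold higher. Interferon-stimulated genes (32 of 45 lower, Irf7 3.84-fold, and 4 higher, Mx2 5.05-fold; 8.45e-05), MHC genes (27 of 34 lower, Ciita 4.05-fold, and 4 higher, H2-Bl 4.99-fold; 0.000426) also moved down. The same held for dendritic cell markers (13 of 22 lower, Tlr9 5.61-fold, and 3 higher, Naaa 1.51-fold; 0.0114), chromatin modifiers (27 of 48 lower, Arid1a 2.75-fold, and 4 higher, Hdac6 1.82-fold; 0.000311) and ciliated cell markers (16 of 24 lower, Spata18 2.36-fold, and 3 higher, Rsph1 2.65-fold; 0.0269). Oxidative phosphorylation (40 of 42 higher, Cox7a2 2.02-fold; 3.52e-10), the glucocorticoid response (16 of 20 higher, Angptl4 3.53-fold, and 1 lower; 1.60e-05) moved up. Further lists that moved up were ribosomal proteins (34 of 48 higher, Rpl37 2.81-fold, and 3 lower, Rps2 3.96-fold; 1.60e-05) and heat shock genes (20 of 32 higher, Pdia6 1.67-fold, and 1 lower, Bag3 1.64-fold; 8.23e-05). So did glutathione and NRF2 targets (29 of 52 higher, Ggt1 4.83-fold, and 6 lower, Txnrd1 1.55-fold and Gclm 1.70-fold; 0.000173), alveolar macrophage markers (11 of 20 higher, Fabp1 4.99-fold, and 3 lower, Ear2 2.33-fold and Krt79 36.0-fold; 0.0296) and neuroendocrine markers (8 of 15 higher, Calca 7.47-fold, and 2 lower, Ddc 2.01-fold and Scg5 1.74-fold; 0.0389). Adjusted over the list alone the counts were the same, except for 41 oxidative phosphorylation, 35 ribosomal and 12 alveolar macrophage genes higher. With an estimated correlation none of these 14 lists passed (adjusted p at least 0.812). Neuroendocrine markers did not pass without number 8 (0.0557), nor did ciliated cell (0.463) and alveolar macrophage markers (0.0783) without numbers over 100. There the calls of the list members Sdc1, Ddc, Scg5, Gclm, Spata18, Bag3, Naaa and Txnrd1 also ended (adjusted p = 0.792, 0.626, 0.207, 0.135, 0.115, 0.089, 0.0638 and 0.0549). The other 27 lists did not pass, among them phase I enzymes (16 higher and 6 lower of 42; 0.332) and p53 targets (12 and 12 of 44; 0.698).

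To determine whether the strain differences held under BD, the 6 libraries labelled CAST/EiJ BD were compared with 6 C57BL/6J BD libraries. In total 6025 genes passed, 2984 higher and 3041 lower in CAST/EiJ, and 1502 differed at least 2-fold. Of these, 2397 higher and 2275 lower genes were shared with clean air, against 864 and 926 by chance (odds ratios 18.2 and 11.2), and 48 changed direction. Across genes, which are not independent replicates, the folds correlated at r = 0.832 (Spearman 0.733). Lists that passed were ciliated cell markers (18 of 24 lower and 1 higher, 19 and 1 adjusted over the list alone; camera adjusted p = 1.10e-06), T and NK cell markers (19 of 34 lower; 3.45e-06), club cell markers (15 of 20 lower and 2 higher; 2.61e-05) and interferon-stimulated genes (24 of 45 lower and 4 higher, 26 and 5 adjusted over the list alone; 8.60e-05). Erythroid markers (10 of 24 lower; 0.00228), glutathione and NRF2 targets (23 of 52 higher and 5 lower; 0.00228), neutrophil markers (10 of 16 higher; 0.0052), inflammatory cytokines (18 of 40 higher and 5 lower; 0.0305) and heat shock genes (7 of 32 higher and 2 lower; 0.039) passed as well. MHC genes passed downward (20 of 34 lower and 5 higher; 0.00229) with a median log2 fold of -0.60 and a mean of -0.06. Inflammatory cytokines did not pass without number 8 (0.0745). With an estimated correlation none of these 10 lists passed (adjusted p at least 0.981), and 31 lists did not pass, B and plasma cell markers (0.37) and the glucocorticoid response (0.246) among them.

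To determine which BD effects differed between the strains, the interaction was tested over all 24 libraries. Some genes that rose in C57BL/6J had a smaller BD ratio in CAST/EiJ. The ratio of ratios was 5.94-fold lower for Fam107a (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00214) and 5.05-fold lower for Fkbp5 (adjusted p = 0.00925). Clean-air CAST/EiJ already held Fam107a at 77.2 ± 18.9 CPM (SD, n = 7), above the 56.5 ± 14.9 CPM (SD, n = 6) of C57BL/6J under BD. The ratio was larger in CAST/EiJ for the chemokine Ccl22 (6.64-fold), the anion exchanger Slc26a4 (6.40-fold), the immediate early gene Nr4a1 (4.35-fold) and the B cell genes Fcer2a (4.53-fold) and Ebf1 (1.90-fold). In total 2035 genes passed, 1238 with a larger and 797 with a smaller ratio in CAST/EiJ, and 361 differed at least 2-fold. Without numbers over 100, 7 genes passed, and with the number series as a covariate 23, of which 22 were among the 2035. Of 46 named calls 45 ended without numbers over 100, all but Cldn2, and 39 ended with the covariate, all but Fam107a, Amigo1, Nhsl1, Rel, Elmsan1, Adh1 and Tet3. Without these libraries the interaction adjusted p of Fam107a, Fkbp5 and Slc26a4 was 0.06, 0.113 and 0.182, the highest over 33 alternatives of each.

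The highest ratios were those of Iigp1 (117-fold), Clec12b (39.6-fold), Skint3 (34.5-fold), Cacna1i (14.3-fold), Ccl22, Chia1 (6.63-fold), Slc26a4 and Fam169b (5.75-fold), and without number 8 Iigp1 (adjusted p = 0.308, turned downward), Skint3 (0.164) and Fam169b (0.0562) did not pass. There the ratio was 10.4-fold for Clec12b, 3.94-fold for Cacna1i and 2.52-fold for Chia1, and the fitted ratios of Iigp1, Clec12b and Skint3 are unstable because their clean-air CAST/EiJ means (0.159, 0.00835 and 0.0315 CPM) lay under the floor of 3 counts per library. The lowest were those of Fam107a, Fkbp5, the adrenaline-forming enzyme Pnmt (4.42-fold), Gdf15 (3.65-fold), Calca (3.39-fold), Rgcc (3.31-fold), Cldn2 (2.96-fold) and Mettl21e (2.82-fold). The smallest p-values also included Amigo1 (1.72-fold larger), Nhsl1 (2.13-fold), the NF-kappaB subunit Rel (3.08-fold) and Elmsan1 (1.91-fold). Ephx1 (1.36-fold) and Gstt1 (1.37-fold) had smaller ratios in CAST/EiJ, and Gstm1 (adjusted p = 0.0821), Cdkn1a (1.86-fold smaller, 0.098) and Cyp2e1 (0.369) did not pass. Cdkn1a passed without CAST/EiJ BD replicate 3 (0.0415), C57BL/6J BD replicate 6 (0.0353) or C57BL/6J clean-air replicate 1 (0.0454). The number of genes was 1265, 577 and 842 without C57BL/6J clean-air replicates 2, 3 and 4, 3547 without replicate 1, 1228 and 978 without C57BL/6J BD replicates 4 and 5, and 1280, 1302 and 3478 without CAST/EiJ clean-air replicates 4, 5 and 6. C57BL/6J clean-air replicate 3 ended 12 of the calls of this comparison (adjusted p 0.0505–0.0796): Pnmt, Cacna1i, Gdf15, Iigp1, Fam169b, Skint3, Chia1, Cldn2, Ephx1, Gstt1, Gsta3 and the complex III subunit Uqcrc2. Chia1, Ephx1, Gstt1 and Skint3 ended without any of 11, 15, 10 and 12 libraries, Iigp1 without 9, Fam169b without 6, Gdf15 without 5 and Cldn2 without 4.

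By gene list 20 interaction tests passed with the preset correlation. The BD ratio was larger in CAST/EiJ for T and NK cell markers (12 of 34, Tcf7 2.38-fold and Lef1 2.24-fold, 17 adjusted over the list alone; camera adjusted p = 1.26e-07), B and plasma cell markers (14 of 23, and 1 smaller, 18 and 1 adjusted over the list alone; 1.17e-07), chromatin modifiers (16 of 48, Tet3 2.08-fold and Crebbp 1.84-fold, 18 adjusted over the list alone; 7.61e-07). The same held for immediate early genes (8 of 27, Nr4a1, and Fosl2 1.55-fold, 11 and 1 smaller adjusted over the list alone; 0.000221), dendritic cell markers (7 of 22, Ccl22, and Ccr7 3.03-fold, 8 adjusted over the list alone; 0.000347) and inflammatory cytokines (4 of 40, Csf1 1.47-fold, 6 adjusted over the list alone; 0.0197). It was smaller for oxidative phosphorylation (12 of 42, Uqcrc2 1.33-fold, 34 adjusted over the list alone; 1.79e-13), the glucocorticoid response (10 of 20, Angptl4 2.79-fold, 13, and 1 larger, adjusted over the list alone; 1.56e-07), phase I enzymes (12 of 42, Adh1 1.67-fold and Akr1c14 2.73-fold, 14 adjusted over the list alone; 1.29e-05). Cell cycle (5 of 50, Mcm2 1.60-fold and Mcm5 1.53-fold, 3 adjusted over the list alone; 0.00363) and heat shock genes (6 of 32, Pdia6 1.46-fold, and 1 larger, 11 and 1 adjusted over the list alone; 0.00048) moved the same way. Ribosomal proteins passed downward without a passing member (0 of 48, 0 adjusted over the list alone; 4.21e-08). Glutathione and NRF2 targets (10 of 52 smaller, Gsta3 1.59-fold, and 1 larger; 0.0132), nucleotide excision repair (4 of 30 smaller, Rpa1 1.25-fold, and 1 larger; 0.0197), hypoxia response (4 of 29 smaller; 0.0228), erythroid markers (9 of 24 smaller, Bpgm 1.38-fold, and 1 larger; 0.0362), neuroendocrine markers (2 of 15 smaller, Calca among them; 0.0464), ciliated cell markers (3 of 24 smaller; 0.0478), fibroblast markers (4 of 21 smaller, Dpt 1.52-fold; 0.0478) and smooth muscle markers (3 of 20 smaller and 3 larger, Notch3 1.79-fold; 0.0495) passed more narrowly. Library number 8 had the highest T and NK score (2.54, others 0.48–1.42) and B and plasma score (3.97, others 2.13–3.065) of its group. Without it 9 of 34 T and NK cell markers and 3 of 23 B and plasma cell markers had a larger ratio, the median log2 ratios were 0.64 and 1.18 in place of 1.00 and 1.46, and both lists passed (1.33e-05 and 1.07e-06). Neuroendocrine (0.0514), erythroid (0.0516) and smooth muscle markers (0.0705) did not pass without number 8, nor did nucleotide excision repair (0.357), fibroblast markers (0.514), erythroid markers (0.294) and hypoxia response (0.1) without numbers over 100. With an estimated correlation none of these 20 lists passed (adjusted p at least 0.444), and p53 targets (0.219) and MHC genes (0.0501) did not pass.

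To determine how BD changed miRNAs in C57BL/6J, 4 BD small RNA libraries were compared with 5 clean-air libraries. The p53-induced miR-34a-5p rose 2.24-fold, from 91.0 ± 15.7 (SD, n = 5) to 204 ± 52.4 CPM (SD, n = 4; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.000982). The lymphocyte miRNA miR-150-5p fell 2.41-fold, from 4241 ± 828 (SD, n = 5) to 1762 ± 543 CPM (SD, n = 4; adjusted p = 0.00184), and the haematopoietic miR-142-3p fell 1.85-fold, from 902 ± 166 (SD, n = 5) to 488 ± 63.8 CPM (SD, n = 4). Of 320 miRNAs 89 passed, 56 higher and 33 lower, and without the clean-air library numbered over 100 there were 85, 42 higher and 43 lower. The ciliated cell miRNAs miR-449c-5p (2.35-fold) and miR-449a-5p (2.29-fold), miR-24-3p (2.10-fold for both loci), miR-500-3p (1.91-fold), miR-22-5p (1.84-fold) and miR-33-5p (1.84-fold) rose, and miR-130b-5p (2.37-fold), miR-342-5p (2.32-fold), miR-423-5p (2.16-fold), miR-3096b-5p (1.98-fold) and miR-582-5p (2.08-fold) fell. miR-449c-5p did not pass without clean-air replicate 3 (adjusted p = 0.0532), and miR-449a-5p ended on leaving out any of 9 libraries (up to 0.15, without BD replicate 3). Haematopoietic miRNAs fell as a list (7 of 13, 9 adjusted over the list alone; camera adjusted p = 4.48e-05, and adjusted p = 0.0479 with an estimated correlation). The other 13 lists did not pass, smooth muscle and mesenchymal (6 of 23 rose; 0.0502), erythroid (0.305, miR-451 1.86-fold and miR-144-3p 1.75-fold higher), p53-linked (0.395) and the miR-17 to miR-92 family (0.977, 6 rose and 4 fell) among them. With the split of the small RNA libraries by number as a covariate 63 miRNAs passed, 36 of them among the 89, and 9 of 24 named calls ended. Among these were miR-150-5p (adjusted p = 0.0597, the highest over 32 alternatives), miR-449c-5p (0.108), miR-130b-5p (0.121), both loci of miR-24-3p (0.287) and miR-449a-5p (0.515).

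To determine the same in CAST/EiJ, 4 small RNA libraries labelled CAST/EiJ BD were compared with 7 clean-air libraries. The smooth muscle miRNA miR-143-3p, the most abundant of those named, fell 1.49-fold from 169900 ± 16390 (SD, n = 7) to 114400 ± 9320 CPM (SD, n = 4; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00169) and passed in all 32 alternatives. miR-335-3p rose 1.81-fold from 93.3 ± 14.3 (SD, n = 7) to 169 ± 13 CPM (SD, n = 4; adjusted p = 0.00169) and miR-335-5p 1.56-fold. Neither passed without numbers over 100 (adjusted p = 0.0626 each; ranges over 32 alternatives 1.74e-06–0.139 and 1.04e-05–0.333), and 12 of the 13 calls of this comparison ended there, as they did with the number series or the split as a covariate. Of 320 miRNAs 13 passed, 8 higher and 5 lower, and 82 had an unadjusted p under 0.05. DESeq2 gave 33. The others were miR-351-5p (1.80-fold), both copies of miR-450a-5p (1.59-fold and 1.55-fold), miR-484 (1.55-fold), miR-191-5p (1.51-fold) and miR-151-5p (1.36-fold), which rose, and miR-210-3p (1.31-fold), miR-107-3p (1.30-fold) and both copies of miR-103-3p (1.31-fold and 1.29-fold), which fell. miR-351-5p did not pass without number 8 (adjusted p = 0.0687), and the other 9 ended on leaving out any of 8–17 libraries. The number was 29 without clean-air replicate 7, 22 without C57BL/6J BD replicate 4, 4 without any 1 of clean-air replicates 1 to 5 or of BD replicate 1, and 5 without BD replicate 2 or 4. The Dlk1-Dio3 cluster moved down (0 of 14 fell over all miRNAs, 7 adjusted over the list alone; camera adjusted p = 0.000626, 0.055 without number 8 and 0.427 with an estimated correlation), and 13 lists did not pass.

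**Figure D5:**
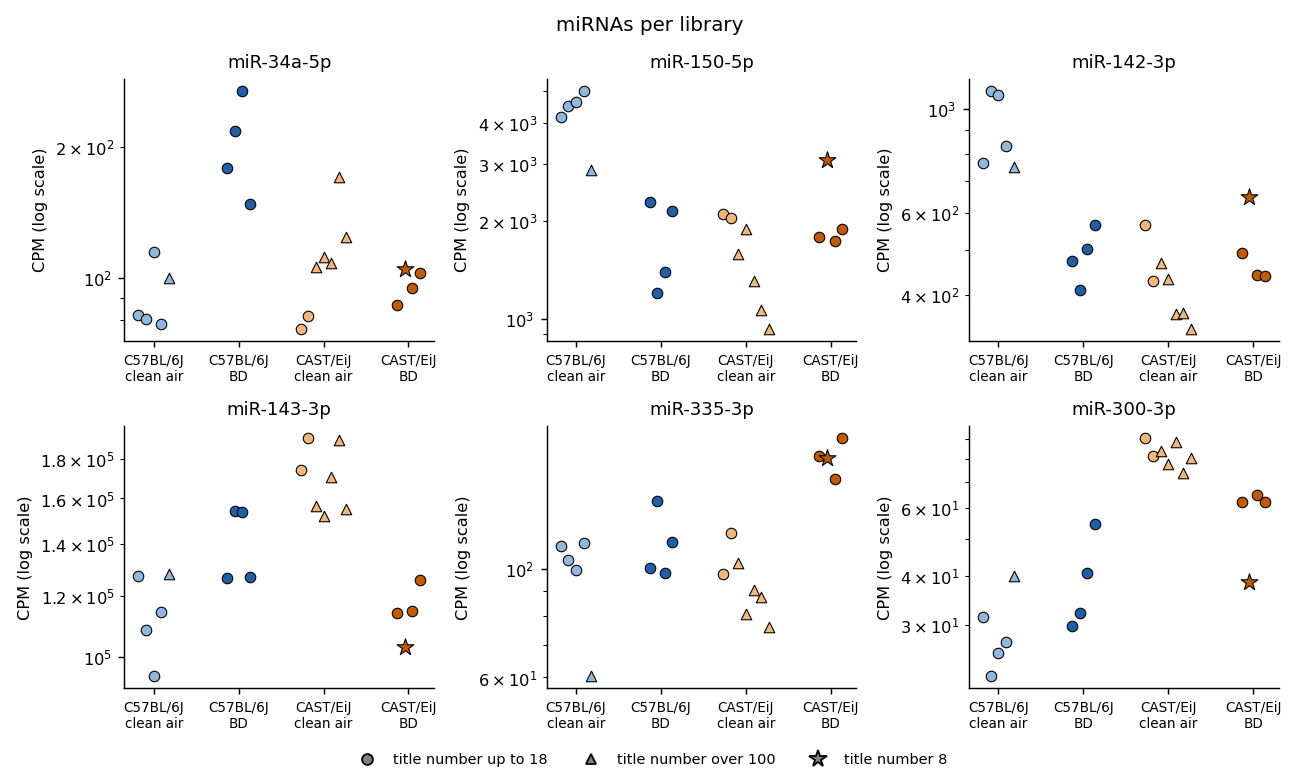
Each point is the level of 1 miRNA in 1 small RNA library, in CPM on a log scale. miR-150-5p was lower in C57BL/6J under BD (1762 ± 543 CPM, SD, n = 4) than in clean air (4241 ± 828 CPM, SD, n = 5).

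To determine which miRNAs differed between the strains and in their BD response, the remaining contrasts were tested. In clean air 127 of 320 passed, 67 higher and 60 lower in CAST/EiJ. miR-146b-5p (3.91-fold, 470 ± 68.2 CPM, SD, n = 5, to 1841 ± 1162 CPM, SD, n = 7), miR-708-5p (2.87-fold), miR-300-3p (2.83-fold; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.68e-06), miR-1247-5p (2.81-fold), miR-136-3p (2.71-fold) and miR-125b-2-3p (1.95-fold) were higher. Lower were miR-1298-5p (4.84-fold), miR-153-3p (3.96-fold), miR-879-5p (3.02-fold), miR-150-5p (2.72-fold), miR-652-3p (2.70-fold), miR-142-5p (2.32-fold) and miR-142-3p (2.13-fold). The imprinted Dlk1-Dio3 cluster, which holds miR-300 and miR-411, was higher in 13 of 14 members (13 adjusted over the list alone; camera adjusted p = 1.54e-08, and adjusted p = 0.127 with an estimated correlation). Under BD 119 passed, 52 higher and 67 lower, and 5 of 14 Dlk1-Dio3 members were higher (adjusted p = 0.0453, 0.0745 with the split as a covariate and 0.405 with an estimated correlation). Without numbers over 100 the clean-air count was 54, with miR-1298-5p not passing (0.0565), and with the split by number as a covariate the count under BD was 62. The interaction passed for 89 miRNAs, 38 with a larger and 51 with a smaller BD ratio in CAST/EiJ. The ratio was larger for miR-130b-5p (4.05-fold), miR-150-5p (3.28-fold), miR-351-5p (2.50-fold), miR-3096b-5p (2.37-fold) and miR-18a-3p (2.33-fold). It was smaller for miR-449a-5p (2.99-fold), miR-29c-5p (2.77-fold), miR-200a-3p and miR-24-3p (2.62-fold each), miR-34a-5p (2.57-fold), miR-500-3p (2.28-fold), miR-19b-2-3p (1.92-fold) and miR-143-3p (1.82-fold). Without numbers over 100, 7 passed, and with the split as a covariate 6. Of 18 named calls 15 ended without numbers over 100, all but miR-130b-5p, miR-150-5p and miR-143-3p, and 17 with the split as a covariate, all but miR-143-3p. miR-449a-5p ended on leaving out any of 13 libraries (adjusted p up to 0.122, without C57BL/6J BD replicate 3). Haematopoietic miRNAs moved up (8 of 13, miR-142-3p 2.21-fold; camera adjusted p = 0.000649), and smooth muscle and mesenchymal miRNAs (7 of 23, miR-29b-1-3p 2.26-fold, 8 adjusted over the list alone; 0.0099) and the Dlk1-Dio3 cluster (4 of 14, miR-136-5p 2.10-fold and miR-300-3p 1.95-fold, 5 adjusted over the list alone; 0.0099) moved down. With an estimated correlation their adjusted p was 0.121, 0.129 and 0.306, and without number 8 the Dlk1-Dio3 cluster did not pass (0.0637).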

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

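The tests on library number 8, on ribosomal and oxidative phosphorylation genes, and on the split of the small RNA libraries by number were chosen only after the results were seen, whereas the regrouping, sequencing depth and number-matched tests were planned. Values in a group were marked when the gap between an extreme library and its neighbour made up a large part of the group's range (a Dixon ratio), which chance marks in about 1 in 20 groups. Of 236 totals, indices and list scores 15 were marked, against 11.8 expected, and of 452 groups of named genes and miRNAs 59, against 22.6 expected. The first number lies near chance, so a mark says little unless other libraries share it.

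The library labelled CAST/EiJ BD replicate 5 (number 8) had a strain index of 0.116 in RNA-seq and 0.171 in small RNA. It lay within the C57BL/6J ranges (-0.0789 to 0.185 and -0.139 to 0.443), below the other CAST/EiJ BD libraries (0.868–0.967 and 0.816–0.851). A swap with a library labelled C57BL/6J was argued against: 0 such libraries had an index above 0.5. A mixture of RNA was argued against by a median share of -0.000588 of the CAST/EiJ level over 110 genes at least 8-fold higher in CAST/EiJ (quartiles -0.025 and 0.0378). Over 135 genes lower in CAST/EiJ the share was 0.164, a bound wrongly chosen, since a C57BL/6J BD library reached 0.244. The index in both assays argues against the CAST/EiJ label and leaves a single wrong label, of a C57BL/6J mouse under BD. The file treated the library as CAST/EiJ (0 of 21 genes unlisted there listed in it), as files made by label would.

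Ribosomal protein genes fell under BD in CAST/EiJ, and the number series of the clean-air libraries may account for it. Within clean-air CAST/EiJ their median log2 difference was 0.458 between numbers over 100 and numbers 1 and 2. Against numbers 1 and 2, and without number 8, their median log2 fold under BD was 0.0339 (quartiles -0.0271 and 0.094). With number 8 kept it was -0.0598 (quartiles -0.162 and 0.0141), so against numbers 1 and 2 alone the fall of 0.401 was not seen. For oxidative phosphorylation genes these values were 0.133 and -0.173 (quartiles -0.203 and -0.0961), so a fall under BD stayed open, and the share of the number series cannot be told apart from it with 2 such clean-air libraries. What the number series stands for was not given in the sources used here.

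miRNA calls of BD in C57BL/6J may hold a part that follows the split of the small RNA libraries by number. The difference of CAST/EiJ clean-air libraries across the split correlated across miRNAs with that of C57BL/6J BD against clean-air numbers 3 to 6 (r = 0.455, Spearman 0.446), and not with BD against clean-air replicate 1, numbered over 100 (r = -0.107). Sequencing depth was argued against, because 79 miRNAs passed after thinning every library to the smallest total. Thinning cannot test what else may part BD replicates 1 to 3 from other libraries. With the split as a covariate 36 of the 89 calls were made again. Exposure and the split cannot be told apart for the rest, because only replicate 1 of the C57BL/6J clean-air libraries lies on the side of the BD libraries.

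The other marked libraries follow. The small RNA total of C57BL/6J BD replicate 4 was 3.146 in units of 1e+06 counts, against 7.677–8.474 in the other 3. The other groups held 2.07–4.18, so those 3 libraries stood apart. In C57BL/6J clean-air replicate 1 the list scores, as mean log2 CPM, were 5.48 for glutathione and NRF2 targets (others 5.17–5.26), 3.25 for base excision repair (3.42–3.46), 6.65 for heat shock genes (5.78–5.89), 3.25 for basal and squamous markers (from -1.19 to -0.69) and 7.30 for ribosomal proteins. In CAST/EiJ BD the marked scores were 2.40 for cell cycle in replicate 3, 4.15 for immediate early genes in replicate 4 and 6.43 for ribosomal proteins in replicate 5. In clean-air CAST/EiJ they were 4.03 for interferon-stimulated genes in replicate 6 and 2.92 for inflammatory cytokines in replicate 5. The score was 5.15 for alveolar macrophage markers in C57BL/6J clean-air replicate 3 and 2.43 for neutrophil markers in C57BL/6J BD replicate 1. Named genes and miRNAs with a marked library numbered 10 in clean-air C57BL/6J, 11 in C57BL/6J under BD, 10 in clean-air CAST/EiJ and 28 in CAST/EiJ under BD, 27 of the last through number 8.

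Differences of the BD response between the strains were marked for 2035 genes and 89 miRNAs. The lists had median log2 ratios of -0.42 (phase I enzymes), -0.24 (glutathione and NRF2 targets), -0.15 (nucleotide excision repair), -0.22 (cell cycle), 0.41 (inflammatory cytokines), -0.73 (glucocorticoid response), 0.48 (immediate early genes), -0.26 (heat shock), 0.27 (chromatin modifiers) and -0.22 (ciliated cells). Further lists stood at -0.38 (neuroendocrine), -0.39 (fibroblast), -0.36 (smooth muscle), 1.00 (T and NK cells), 1.46 (B and plasma cells), 0.74 (dendritic cells), -0.42 (erythroid), -0.41 (ribosomal proteins), -0.39 (oxidative phosphorylation) and -0.21 (hypoxia). The miRNA lists stood at 0.75 (haematopoietic), -0.42 (smooth muscle) and -0.56 (Dlk1-Dio3). The log2 ratios of named genes were 6.87 (Iigp1), 5.31 (Clec12b), 5.11 (Skint3), 3.84 (Cacna1i), 2.73 (Ccl22), 2.73 (Chia1), 2.68 (Slc26a4), 2.52 (Fam169b), 0.79 (Amigo1), 1.09 (Nhsl1), 1.62 (Rel) and 0.93 (Elmsan1). Lower were -2.57 (Fam107a), -2.34 (Fkbp5), -2.15 (Pnmt), -1.87 (Gdf15), -1.76 (Calca), -1.73 (Rgcc), -1.57 (Cldn2), -1.49 (Mettl21e), -0.44 (Ephx1) and -0.46 (Gstt1). Among miRNAs they were 2.02 (miR-130b-5p), 1.71 (miR-150-5p), 1.32 (miR-351-5p), 1.25 (miR-3096b-5p), 1.22 (miR-18a-3p), -1.58 (miR-449a-5p), -1.47 (miR-29c-5p), -1.39 (miR-200a-3p and both loci of miR-24-3p), -0.86 (miR-143-3p), -1.19 (miR-500-3p) and -0.94 (miR-19b-2-3p). Some miRNAs were listed by group, 5, 1 and 4 of them in patterns given below.

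To weigh chance, other splits of these libraries were drawn, and for 10 results none gave as many calls. Such splits mix real groups and number series, which can widen the pooled spread and lower their counts. Splits by number series reached the real count for BD in CAST/EiJ (below) and were not run for the interaction. For BD in C57BL/6J the real value and the highest other value drawn were 1298 and 372 genes, and 89 and 64 miRNAs, the 64 from a split that moved clean-air replicate 1 to BD. For BD in CAST/EiJ they were 2390 and 1606 genes, and 13 and 2 miRNAs, and for the interaction 2035 and 21 genes and 89 and 30 miRNAs. Between the strains they were 10316 and 5738 genes and 127 and 37 miRNAs in clean air, and 6025 and 2001 genes and 119 and 31 miRNAs (35 splits) under BD. The splits with 5738, 2001 and 31 calls still parted most libraries by strain, and the split with 37 placed 5 of 6 libraries numbered over 100 together and also parted the strains in part. Chance is not the only alternative to exposure. Of 15 splits of the CAST/EiJ RNA-seq libraries that put the 5 numbered over 100 with 2 BD libraries against the rest, 7 gave at least 2390 genes (112–3800), so a grouping by number series gave as many calls as the real one, and with that series as a covariate 200 genes passed. For miRNAs in CAST/EiJ 1 of 6 such splits gave at least 13 (0–15), and in C57BL/6J none of 6 (0–607 genes) or 4 (0–67 miRNAs) did.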

How the results depend on the processing

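Settings without number 8, with the small RNA split or with more than 1 change were added after the data were seen. Those without numbers over 100 or with the series as a covariate were planned. The cause of each shift was not tested unless a pattern above names it. No paired analysis was possible because within an assay no groups share a title number, and the replicate numbers have no order across groups. The groups held 4–7 libraries. miRNAs unlisted in some libraries were not tested. BD and number series overlap in part in both strains, and the series was a covariate through 6 clean-air libraries alone.

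With the compared groups alone in the fit 2434 genes passed for BD in C57BL/6J (1298 with all groups), 159 for BD in CAST/EiJ (2390) and 7 miRNAs for BD in CAST/EiJ (13). DESeq2 gave 33 there. Limma-voom, median-of-ratios factors and no filter on low counts moved no count of genes or miRNAs by more than 1.5 times. Of the named genes, limma-voom ended 12 of 46 interaction calls (Iigp1, Skint3, Cacna1i, Chia1, Slc26a4, Fam169b, Pnmt, Gdf15, Calca, Cldn2, Ephx1 and Gstt1). The fit with no filter ended 3 of 46 interaction calls (Skint3, Chia1 and Ephx1), 4 of 50 for BD in CAST/EiJ (Gabra3, Krt79, Keg1 and Cyp4a12a) and 1 of 41 for BD in C57BL/6J (Cyp4f18). Larger losses came from the compared groups alone (25 of 43 genes and 7 of 13 miRNAs for BD in CAST/EiJ), the series as a covariate (35 of 50 genes and 12 of 13 miRNAs for BD in CAST/EiJ, 39 of 46 interaction genes) and leaving out numbers over 100 (35 of 50, 12 of 13 and 45 of 46, and 10 of 70 genes between strains in clean air). With at least a 2-fold difference required in each exposure, the strain overlap was 1214 genes (4672 without that bound). With an estimated correlation 3 gene list tests passed (76 with the preset) and 1 miRNA list test (7 with the preset), and fry gave 30 miRNA list tests and ended 24 of the 76 gene list calls.

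When numbers over 100 were left out, 1971 genes passed for BD in C57BL/6J, 382 for BD in CAST/EiJ, 6820 between strains in clean air (10316) and 7 for the interaction (2035). The miRNA counts were 5 for BD in CAST/EiJ, 54 between strains in clean air (127) and 7 for the interaction (89). The overlap of BD calls was 39 genes (135), and 13 miRNA list tests passed. The test of double-strand break, crosslink and mismatch repair for BD in CAST/EiJ turned downward, at a median log2 fold of 0.000937 (adjusted p = 0.742, range over 6 alternatives 0.0163–0.904). With the number series as a covariate 2442 genes passed for BD in C57BL/6J, 200 for BD in CAST/EiJ and 23 for the interaction, 4 miRNAs for BD in CAST/EiJ, and the BD overlap was 57. Under this covariate the folds of both strains share 1 estimated coefficient, so overlaps between strains there are not comparable with the others.

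Without number 8 the gene count for BD in CAST/EiJ was 1255. There the test of T and NK cell markers turned downward, at a median log2 fold of 0.0300 (adjusted p = 0.853, range over 6 alternatives 0.0413–0.859). Iigp1 was reversed to a log2 fold of -1.88, Gabra3 to -0.82 and Krt79 to -0.11, and Iigp1 to -1.12 in the interaction. Leaving out any other library gave up to 6.38, 4.83 and 3.31 for these genes and up to 7.14 for the interaction. Without number 8 and with the series as a covariate the gene counts were 3368, 275 and 84 for BD in C57BL/6J, BD in CAST/EiJ and the interaction, 6 miRNAs passed for BD in CAST/EiJ, 14 miRNA list tests passed and the BD overlap was 87. Reversed in BD in CAST/EiJ were T and NK cell markers (-0.15), double-strand break, crosslink and mismatch repair (-0.00623), cytosolic ribosomal proteins (0.0473), Iigp1 (-1.62), Olfr1033 (-0.0748), Gabra3 (-1.02) and Tmem132d (-0.13), and Iigp1 in the interaction (-0.94). Without number 8 and numbers over 100 the gene counts were 3016, 627 and 320, 73 miRNAs passed between strains in clean air and 12 in the interaction. Reversed in BD in CAST/EiJ were Iigp1 (-2.20), Olfr1033 (-1.02), Gabra3 (-2.18), Tmem132d (-0.25), Trim30d (-0.56) and Gpx1 (0.0406), and Iigp1 in the interaction (-1.54).

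With the split of the small RNA libraries as a covariate 4 miRNAs passed for BD in CAST/EiJ, 62 between strains under BD (119) and 6 for the interaction, and 12 list tests passed. Without number 8 as well, 6 passed for BD in CAST/EiJ, 9 for the interaction and 15 list tests, and miR-449a-5p turned to 0.18 in the interaction. Over all alternatives 8630 values of printed genes and miRNAs kept their direction and their side of the threshold, 818 lost their call, 14 gained one and 17 were reversed, and for lists the first, second and last numbers were 361, 146 and 5. The squamous and liver scores as covariates ended 7 of 46 interaction calls (Iigp1, Skint3, Chia1, Fam169b, Gdf15, Ephx1 and Gstt1), 2 of 50 for BD in CAST/EiJ (Gabra3 and Krt79) and 1 of 41 for BD in C57BL/6J (Cyp4f18). Unlisted values taken as 0 ended miR-18a-3p in the interaction, and taken as 5 miR-449a-5p in the interaction and for BD in C57BL/6J. None of these settings reversed a printed value.

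Leaving out 1 library gave 570–1857 genes for BD in C57BL/6J (lowest without clean-air replicate 3), 808–3810 for BD in CAST/EiJ (without clean-air replicates 4 and 6) and 577–3547 for the interaction (without C57BL/6J clean-air replicates 3 and 1). It was 9437–10591 between strains in clean air and 5043–7417 under BD, where no library moved the count by more than 1.5 times. For miRNAs the range was 61–115 for BD in C57BL/6J, 4–29 for BD in CAST/EiJ (29 without clean-air replicate 7), 108–140 and 86–144 between strains in clean air and under BD. For the interaction the lowest count was 68, without C57BL/6J BD replicate 3, and no library moved it by more than 1.5 times.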

Other observations

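For some genes the level in library number 8 lay with the libraries of its label and not with C57BL/6J. In it Ddx3x was at 524 CPM, against 552 ± 50.1 CPM (SD, n = 5) in the other libraries labelled CAST/EiJ BD and no counts in C57BL/6J under BD (n = 6). Amer1 was at 56.9 CPM in it, against 51.9 ± 8.12 (SD, n = 5) in those libraries and 0.228 ± 0.188 CPM (SD, n = 5) in clean-air C57BL/6J. The glycolytic gene Gapdh was at 2.68 CPM in it, against 3.90 ± 0.387 (SD, n = 5) and, in C57BL/6J under BD, 26.9 ± 3.14 CPM (SD, n = 6). Of 110 genes at least 8-fold higher in CAST/EiJ 4 stood above 0.5 of the CAST/EiJ level in number 8, both Mir692 copies among them (87.3 CPM each). How the files were made for libraries labelled CAST/EiJ was not given in the sources used here.

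miRNAs without a value in some libraries were not tested, and several were listed by strain or by label. The airway miRNA miR-34c-5p held 30690–109900 counts in every C57BL/6J library and was listed in no library labelled CAST/EiJ, number 8 included, and miR-34c-3p (402–1288 counts) had the same pattern. miR-1264-3p, miR-1298-3p (13–64 counts) and miR-489-3p (15–96 counts) were listed in every C57BL/6J library and, among libraries labelled CAST/EiJ, in number 8 alone (46, 14 and 15 counts). miR-196b-5p was listed in every CAST/EiJ library but number 8 (16–39 counts) and in no C57BL/6J library. miR-411-3p, miR-369-5p, miR-501-5p and miR-296-5p were listed in every C57BL/6J BD library, at 11–65.5 counts, and in no C57BL/6J clean-air library, which were smaller than 3 of the 4 BD libraries.

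The hypothesis tests on the pairs of measurements below were planned, and those within the number series were chosen only after the first result was seen. It was a hypothesis that the sampled C57BL/6J lungs held fewer lymphocytes under BD, since lymphocyte genes and haematopoietic miRNAs both fell. Number 8 was left out of these tests after its strain index had been seen. Over the other 19 pairs of libraries of the same title number, deviations from the group means of a score of 57 B, plasma, T and NK cell genes and of the haematopoietic miRNA score correlated at r = 0.812 (Spearman 0.767, permutation p = 2e-04, adjusted over 2 relations 4e-04), and at r = 0.823 without the 2 farthest pairs. Within group and number series (n = 18) r was 0.786 (permutation p = 0.00229), and over numbers up to 18 (n = 13) it was 0.794 (permutation p = 0.0246), with a Spearman correlation of 0.665 (permutation p = 0.0582) and r = 0.549 without the 2 farthest pairs. With number 8 included the values were 0.824 (n = 20, permutation p = 5e-05), 0.804 (n = 19, permutation p = 0.00061) and 0.789 (n = 14, permutation p = 0.00583). A varying share of lymphocytes or of blood in the tissue may therefore account for part of both measurements, and dissection stays open as its source beside BD.

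It was also a hypothesis that p53 activity set both the p53 target genes and miR-34a-5p. Their deviations correlated at r = 0.623 (n = 19, Spearman 0.663, permutation p = 0.015, adjusted over 2 relations 0.015), and at r = 0.59 without the 2 farthest pairs. Within group and number series (n = 18) r was 0.423 (permutation p = 0.208) and 0.0442 without the 2 farthest pairs, whereas over numbers up to 18 (n = 13) it was 0.802 (permutation p = 0.0198, Spearman 0.637 with permutation p = 0.0895, and r = 0.591 without the 2 farthest pairs). With number 8 included r was 0.594 (n = 20, permutation p = 0.0202), 0.382 (n = 19, permutation p = 0.244) and 0.731 (n = 14, permutation p = 0.0371). A shared p53 response and a difference between the number series cannot be told apart here.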
